A study of Homo sapiens with 12 samples.

How the data were processed

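Biotin-labelled total RNA of 3 established cell lines was hybridised by the authors to Affymetrix U133 Plus arrays on a GeneTitan instrument. The probe set names show the version of the array with perfect-match probes only. The deposited values are log2 intensities per probe set, made by the authors with RMA per the labels, which corrects background, quantile normalizes and summarises probes. Software, version and settings of that step are not given in the sources used here. The values run from 2.048 to 13.771, none is missing, and the quartiles of the 12 arrays lie close together, as RMA leaves them. They were used as deposited.

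Groups were taken from the sample titles, which gave 4 groups in 3 lines with no array unassigned. A further line named in the protocol, SW620, has no array in the series and was not analysed here. The arrays hold 54715 probe sets, 102 of them manufacturer's controls. Probe sets that name a single gene (40920) were kept, while 864 that name several genes were left out. Of the 12931 with no gene name, 12835 were tested apart. Each of the 19774 genes was represented by the probe set with the highest mean over all arrays, and 10550 genes had several to choose from. Gene symbols were checked against a RefSeq gene table by Entrez number (40864 matched, 0 symbols changed). Genomic positions were not used here. Of 132 results for named genes with several probe sets, 45 had another probe set of opposite sign, but only in 2 was that probe set above background and over 0.2, both for FN1. In 3 results, those for LOX, DPY19L1 and CDS1 with both clusters, another probe set above background had a change over 1 log2 unit from that of the one used, a count made after the data were seen.

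Comparisons were made with limma 3.58.1 in R 4.3.3, with the data.table package in version 1.17.8, by a linear model with cell line as a fixed term, empirical Bayes moderation with a trend of variance on level, and Benjamini-Hochberg adjustment over all genes at 0.05. All p from limma are two-sided. Samples of the same line are paired through that term. Without it, in other words with no block for the line, 0 genes were called with both clusters against 1214 with it. The 2 HUTU-80 arrays with miR-200c141 were averaged, so that 11 samples entered. Each control, miR-200c141 and miR-200ba429 group had 3 samples and the group with both clusters had 2. Residual degrees of freedom were 5 for the model with 4 groups and for the test between lines, and 7 for any construct against control. The difference between lines was tested with a moderated F over the interaction terms. The number of arrays limits the precision, and each line has a single control array, so an error in it enters every change of that line.

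On simulated data with 100 genes changed by 1 and 100 by 2 log2 units, the fits recovered 94.0% and 99.0% for any construct, 86.0% and 100.0% for miR-200c141, 79.0% and 100.0% for miR-200ba429, and 79.0% and 100.0% for both clusters. For the difference between lines they recovered 16.0% and 88.0%. The number of false calls was between 6 and 14. In the comparisons of groups each simulated change had the same size in every line. The shares recovered therefore do not apply to genes whose change differs between lines, as that of EPCAM did. Camera gave p under 0.05 for 3 of 260 unchanged lists (1 with an estimated correlation) and for 20 of 20 lists shifted by 0.5. These simulated genes varied independently of each other. In the data the estimated correlation for any construct was 0.824 for the cell cycle genes and 0.277 for the epithelial markers. The simulation therefore cannot show how camera at the preset correlation behaves for such lists.

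The groups, tests, 13 gene lists, rule for named genes and alternative settings, apart from those said to be added, were fixed before the data were examined. The lists, from textbook knowledge, hold miR-200 targets, epithelial markers, mesenchymal markers, TGF-beta targets, interferon-stimulated genes, cell cycle genes, p53 targets, Wnt targets, intestinal differentiation genes, neuroendocrine markers, immune cell markers, endothelial cell markers and ribosomal proteins, and share 0 members. They were tested against all other genes with camera at a preset correlation of 0.01 and adjusted over the 52 tests of 4 comparisons with control. Estimated correlations and fry, which asks whether a list moves one way on balance, were alternatives, and no call made with the preset correlation held with either. The lists in the comparisons between constructs were added after the data were seen and adjusted over their own tests. Signs of median, mean and camera direction differed only in lists with no call, for instance for the neuroendocrine markers with miR-200c141 (median 0.049, mean −0.039). The exact permutation of list means exchanged which array of each line is the control, over 48 choices.

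Named genes followed a rule. In each comparison with control these are the 10 largest falls and 10 largest rises among genes past the threshold and changed the same way in every line. Where fewer than 5 passed in a direction, the 5 of smallest p were taken and are said not to have passed. Between constructs the 5 of smallest p were taken, and between lines the 8 of smallest p. Each list gave up to 4 members past the threshold, or the 2 of largest change where none passed. ZEB1, ZEB2, QKI, CDH1, EPCAM, ESRP1, ESRP2, VIM, CDH2 and FN1 are named whatever they did.

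Alternatives tried were no cell line term, the HUTU-80 pair as separate samples or either array alone, the mean of all probe sets of a gene, only genes above the median level (5.190), quantile normalization, median centring, no variance trend, only the groups compared, and each line left out in turn. Without MDST8 or NCI-H716 a single sample with both clusters is left. Any p for both clusters in those fits rests on the spread of the other groups. A fit without the MDST8 array with miR-200ba429 was added after the data were seen. The correlation expected from a shared control array was simulated 100 times from the residual spread. A planned comparison of genes with and without matches to the miR-200 seed sequences was not run, since no 3′ UTR sequence is given in the sources used here.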

Results

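Gene expression was measured on 12 Affymetrix U133 Plus arrays in HUTU-80, MDST8 and NCI-H716, 3 established lines labelled as colorectal cancer with methylated miR-200 loci. The miR-200 family of microRNAs is made from a pair of gene clusters, named here as in the labels miR-200c141 (miR-200c and miR-141) and miR-200ba429 (miR-200b, miR-200a and miR-429), and is known to repress ZEB1 and ZEB2, transcription factors that in turn repress epithelial genes. Cells transduced with lentivirus were sorted for the fluorescent marker after 48 hours, and RNA was taken on day 7. Part of the miR-200ba429 cells received the miR-200c141 virus 24 hours after sorting, which gave cells with both clusters. There were 3 control arrays (1 per line), 4 arrays with miR-200c141 (2 of them from HUTU-80), 3 with miR-200ba429 (1 per line) and 2 with both clusters (MDST8 and NCI-H716). The titles of the 2 HUTU-80 arrays with miR-200c141 end in 1:3 and 1:5; what the ratio stands for, and what the control cells received, is not given in the sources used here. That pair was averaged, which left 11 samples. No other group of a line has a replicate, and the labels do not say whether arrays came from separate cultures, so the errors given are standard errors (SE) of a model fitted over the lines.

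The values are log2 intensities, with array medians from 3.595 to 3.662. Arrays of the same line correlated across genes, each with the probe set used for it, at 0.978 or more, and arrays of different lines at 0.885 or less. The 23 nonspecific control probe sets reached 5.429 at most, which served as the background level. A change between values below it, or from or to such a value, is a difference of signals whose size is limited by background. In the control arrays, CDH1, the epithelial cadherin, lay below background in HUTU-80 (3.20), MDST8 (3.14) and NCI-H716 (4.01). EPCAM, an epithelial adhesion molecule, lay below background in HUTU-80 (4.42) and MDST8 (3.52) and at 9.29 in NCI-H716. ZEB1 stood at 9.87, 9.39 and 10.15 in the same order. The number of arrays limits the precision.

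The first comparison asked what any miR-200 construct changed in lines whose own miR-200 loci are methylated. ZEB1 was lower than in the control of the line on all 9 arrays with a construct, with a fitted log2 change of −1.46 ± 0.33 (SE, 8 samples with a construct against 3 controls). CDH1 stood at 2.22 ± 0.61, EPCAM at 2.59 ± 0.69 and CDS1, an enzyme of phospholipid synthesis on the epithelial list, at 2.61 ± 0.62. These 4 genes did not pass the test across all genes, with adjusted p of 0.4147, 0.4917, 0.4529 and 0.4147. The genes of smallest p, which did not pass either, had changes of −0.79 ± 0.11 for C14orf132, −1.23 ± 0.22 for DDIT4, a stress-responsive inhibitor of mTOR signalling, 0.97 ± 0.16 for AP1S3 and 1.21 ± 0.24 for MYO5B, a motor of apical membrane traffic. ZEB2 stood at −0.80 ± 0.38, QKI, an RNA-binding target of the family, at −0.67 ± 0.28, the splicing regulators ESRP1 and ESRP2 at 1.41 ± 0.76 and 0.28 ± 0.14 (ESRP2 below background on every array and ESRP1 on every array of HUTU-80 and MDST8, with −0.11 for ESRP1 without NCI-H716), and the mesenchymal genes VIM and CDH2 at −0.35 ± 0.18 and −0.21 ± 0.14.

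Of the 51 measured epithelial genes, 49 had a positive change, with a list median of 0.631 and 16 past the threshold when adjusted over the list alone, against 0 over all genes. Camera, a test of a list against all other genes, gave the list an adjusted p of 5.71e-18, and adjusted p = 0.3745 with an estimated correlation. An exact two-sided permutation of which array of each line is the control gave p = 0.0208 for the mean of the list, the smallest that 48 choices allow, and 0.2708 after adjustment over 13 lists. Of the 45 measured miR-200 targets, 34 had a negative change (median −0.231, 1 past the threshold adjusted over the list alone, camera adjusted p = 5.76e-05). For this list adjusted p = 0.7012 with an estimated correlation. Camera also called the cell cycle genes (median −0.154, adjusted p = 0.0013), the intestinal differentiation genes (0.158, 0.010) and the ribosomal proteins (−0.020, 0.0461). For these, in the same order, adjusted p = 0.8485, adjusted p = 0.6626 and adjusted p = 0.7355 with an estimated correlation. The cell cycle list was not called with miR-200c141 (median −0.073, adjusted p = 0.0532) or miR-200ba429 (0.006, 0.7592), and all 40 members were positive in MDST8 with miR-200ba429. Its array medians were −0.59 and −0.32 on the MDST8 and NCI-H716 arrays with both clusters, whose 3′ to 5′ differences, a sign of RNA quality, were the highest of their line, and −0.32 in HUTU-80 with miR-200ba429. The intestinal median was 0.022 without NCI-H716, where camera no longer called it (adjusted p = 0.9887). Of its 36 members, 35 lay at background in the HUTU-80 control and 36 in that of MDST8, so that value compares mostly background signals. The ribosomal call was lost without HUTU-80 (0.0551), MDST8 (0.0698) or NCI-H716 (0.3627). No call was made for mesenchymal markers (median −0.062), TGF-beta targets (0.050), interferon-stimulated genes (−0.020), p53 targets (0.181), Wnt targets (−0.025, with a mean of 0.039), neuroendocrine (−0.006), immune cell (−0.050) or endothelial cell markers (−0.031).

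Limma called 0 of 19774 genes, with a smallest adjusted p of 0.3108, while 1851 genes had an unadjusted p under 0.05, where 989 are expected by chance. The count was 8 without MDST8 and 3 without the MDST8 array with miR-200ba429 alone.

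**Figure D1:**
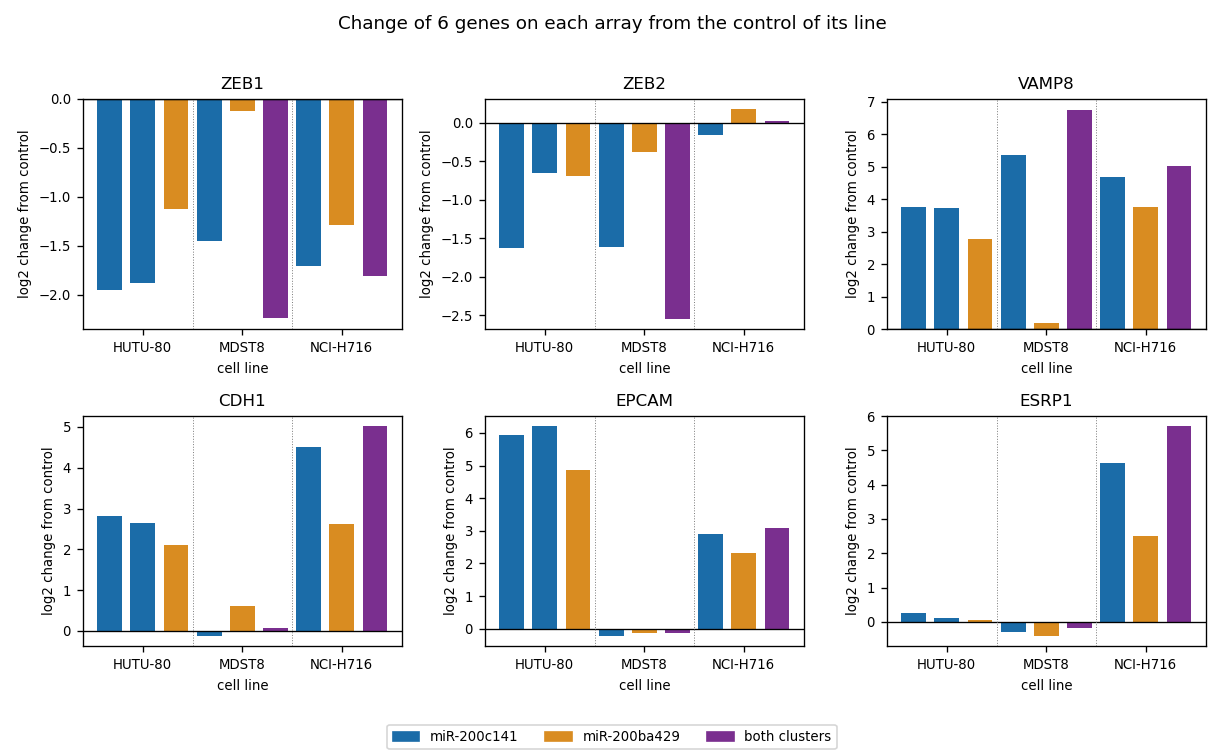
Log2 change from the control array of the same line (vertical axis) for ZEB1, ZEB2, VAMP8, CDH1, EPCAM and ESRP1, with 1 bar per array, grouped by cell line and coloured by construct. ZEB1 bars run from −0.13 to −2.24, and the CDH1 and EPCAM bars of MDST8 stay between −0.22 and 0.62 while those of HUTU-80 and NCI-H716 reach 2.10 or more.

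The second comparison asked what miR-200c141 changed when given alone, over 3 lines. ZEB1 was lower in each line, by −1.91 in HUTU-80, −1.45 in MDST8 and −1.71 in NCI-H716 (fitted −1.69 ± 0.23 SE). VAMP8, a protein of vesicle fusion, stood at 4.59 ± 0.77, and its signal went from 3.70 to 7.45 on the HUTU-80 array titled 1:3, from 2.95 to 8.29 in MDST8 and from 5.01 to 9.70 in NCI-H716. KRT18, a keratin of simple epithelia, stood at 1.39 ± 0.20, GCH1, the first enzyme of tetrahydrobiopterin synthesis, at 0.89 ± 0.12, and the target PPM1F at −1.19 ± 0.18. None of these passed across all genes, with adjusted p of 0.1166 for ZEB1 and GCH1, 0.1272 for KRT18, 0.1805 for PPM1F and 0.2421 for VAMP8. CDH1 was 2.73 above the control in HUTU-80, 4.51 in NCI-H716 and −0.12 in MDST8, and EPCAM showed 6.08, 2.89 and −0.22 in that order. ESRP1 was 4.62 above the control in NCI-H716, against 0.18 in HUTU-80 and −0.31 in MDST8.

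With miR-200c141, 48 of 51 epithelial genes had a positive change (median 0.734), with 0 past the threshold over all genes and 14 adjusted over the list alone. Camera gave this list an adjusted p of 2.40e-21, and adjusted p = 0.3745 with an estimated correlation. Of the miR-200 targets, 35 of 45 had a negative change (median −0.197), 3 of them past the threshold adjusted over the list alone. Camera gave 2.27e-07 after adjustment, and adjusted p = 0.3745 with an estimated correlation. The intestinal differentiation list had a median of 0.178 (camera adjusted p = 0.0087), and adjusted p = 0.6626 with an estimated correlation. Its largest changes were in NCI-H716. There CEACAM5, a cell surface glycoprotein of gut epithelium, was 5.25 and REG4, a secreted lectin of enteroendocrine and goblet cells, 3.43 above the control. Without NCI-H716 the list median was 0.010, where nearly all members lay at background in the controls. Mesenchymal markers were not called (median −0.097, camera adjusted p = 0.0519), and in MDST8 28 of the 49 members were positive (median 0.09). Over the 32 members above background in that line's control or with miR-200c141, 14 were positive and 18 negative (median −0.05).

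Limma called 0 genes, with a smallest adjusted p of 0.1166, and 1302 genes had an unadjusted p under 0.05. The count was 22 without MDST8, 3 with the HUTU-80 arrays as separate samples, 4 when only control and miR-200c141 samples were fitted, and 3 without the MDST8 array with miR-200ba429.

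The third comparison asked the same of miR-200ba429 alone. ZEB1 was at −1.13 in HUTU-80 and −1.29 in NCI-H716 but at −0.13 in MDST8 (fitted −0.85 ± 0.23 SE, adjusted p = 0.7891). EPCAM was 4.86 above the control in HUTU-80, 2.32 in NCI-H716 and −0.14 in MDST8, and CDH1 2.10, 2.63 and 0.62 in that order. VAMP8 was 2.78 above the control in HUTU-80 and 3.75 in NCI-H716, against 0.20 in MDST8. The genes of smallest p included C14orf132 at −0.66 ± 0.12, DDIT4 at −1.08 ± 0.21, GCLM, a subunit of the enzyme that starts glutathione synthesis, at 0.72 ± 0.14, and AP1S3 at 0.83 ± 0.16, which did not pass (adjusted p = 0.7685). PTPRC, also of small p, lay below background on every array (2.69 to 3.83).

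Of the epithelial genes, 43 of 51 had a positive change (median 0.360), with 0 past the threshold over all genes and 0 adjusted over the list alone. Camera called the list at an adjusted p of 4.90e-09, and adjusted p = 0.4574 with an estimated correlation. The interferon-stimulated genes had a median of −0.189, with 30 of 38 negative, among them IFI6 at −0.62 ± 0.41, which did not pass (adjusted p = 0.8216). Camera called that list at an adjusted p of 0.0016, with adjusted p = 0.6626 with an estimated correlation, and adjusted p = 0.1010 without the MDST8 array. The miR-200 targets had a median of −0.090 and no call (camera adjusted p = 0.1365). Limma called 0 genes, with a smallest adjusted p of 0.7685, and 1214 had an unadjusted p under 0.05; without MDST8 the count was 6.

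The fourth comparison asked what both clusters together changed, in MDST8 and NCI-H716. ZEB1 fell by 2.11 ± 0.27 on the log2 scale (SE, 2 samples against 3 controls, adjusted p = 0.0022), with −2.24 in MDST8 and −1.81 in NCI-H716. VAMP8 rose by 5.83 ± 0.89 (adjusted p = 0.0058), from control levels below background (2.95 in MDST8 and 5.01 in NCI-H716) to 9.70 and 10.02. The probe set used for LOX, a collagen-crosslinking enzyme, fell by 2.77 ± 0.39 (0.0037), while another LOX probe set stood at 0.13, with 8.31 in the MDST8 control and 8.58 with both clusters. MMP16, a membrane-bound matrix metalloproteinase, fell by 2.72 ± 0.26 (5.48e-04). Other large falls were VASH2 (−2.73), ZCCHC24 (−2.71), OSTM1 (−2.68), RECK, a membrane inhibitor of metalloproteinases (−2.64), ZFTA (−2.41), DPY19L1 (−2.38), B4GAT1 (−2.35) and TET1, a DNA demethylase (−2.25). Other large rises were CDS1 (3.74), LAMB3, a laminin chain of epithelial basement membranes (3.47), ELOVL7 (3.39), AKR1B10 (3.34), ZNF165 (3.17), EXPH5 (3.16), ARL14 (3.11), TMC4 (3.07) and PATJ, a tight junction scaffold (2.96). EXPH5 was at 1.5 without MDST8 (adjusted p = 0.0996) and CDS1 at 2.49 without NCI-H716 (0.0282), and AKR1B10 had adjusted p = 0.0570 without HUTU-80 and 0.0570 without MDST8. With the mean of all probe sets, values moved closer to 0 for ZEB1 (−1.31), LOX (−1.02), VASH2 (−1.55), ZFTA (−1.18), DPY19L1 (−0.68), CDS1 (2.43) and PATJ (1.17), and MMP16 (−0.59, adjusted p = 0.0677), RECK (−0.75, 0.0633), EXPH5 (1.93, 0.0690) and AKR1B10 (3.34, 0.0597) no longer passed. Besides VAMP8, the controls of both lines lay at background for ELOVL7, AKR1B10, ZNF165, EXPH5, ARL14, TMC4, PATJ, PKP2 and IFI27, and the NCI-H716 control for CDS1 and LAMB3. The same holds of genes named further on, CCN2, HTRA1 and FSTL1 in the NCI-H716 control and GREM1, PLK1 and EPHB3 in that of MDST8. CDH1 at 2.67 ± 0.84 (adjusted p = 0.0909), EPCAM at 2.44 ± 0.99 (0.1755) and ESRP1 at 2.43 ± 0.98 (0.1759) did not pass. In NCI-H716 they were 5.02, 3.10 and 5.71 above the control and in MDST8 0.08, −0.12 and −0.19. Without MDST8 the fitted changes were 4.64, 4.05 and 4.57. Fits without MDST8 or NCI-H716 hold a single sample with both clusters, so their p rest on the spread of the other groups.

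Among the 45 miR-200 targets, 12 fell and 0 rose, and 19 fell when adjusted over the list alone. Beside ZEB1 these included PPM1F, a phosphatase that acts on the cytoskeleton (−2.23 ± 0.21), CFL2, an actin-severing cofilin (−2.16 ± 0.22), and SEC23A, a coat protein of secretory vesicles (−1.82 ± 0.22), and PPM1F was at −0.95 with the mean of all probe sets. Camera gave the list, with a median of −0.450, an adjusted p of 1.20e-09, and adjusted p = 0.3745 with an estimated correlation. ZEB2 at −1.36 ± 0.45 (adjusted p = 0.1048) and QKI at −1.21 ± 0.33 (0.0580) did not pass. ZEB2 was at −2.55 in MDST8 and 0.02 in NCI-H716, where its control lay at 3.19, below background, so that a fall could not be seen. Without NCI-H716, in a fit with a single sample with both clusters, ZEB2 was at −2.52 and QKI at −1.69. FN1, a matrix target with several probe sets that disagree in sign in the comparisons above, stood at −0.40 ± 0.23 (0.3424).

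Of the 51 epithelial genes, 9 rose and 0 fell, and 23 rose when adjusted over the list alone. They included CDS1, TMC4, PATJ and PKP2, a desmosomal plaque protein (2.80 ± 0.43, and 1.48 with the mean of all probe sets). The list median was 1.138, with a camera adjusted p of 2.76e-13 and adjusted p = 0.3745 with an estimated correlation. All 40 cell cycle genes had a negative change (median −0.474), of which 12 fell over all genes and 24 adjusted over the list alone. MCM2, a subunit of the replicative helicase (−1.12 ± 0.21), the spindle checkpoint kinase BUB1B (−1.03 ± 0.18), the mitotic kinase PLK1 (−1.02 ± 0.25) and the spindle motor KIF11 (−1.01 ± 0.24) were among them. PLK1 had adjusted p = 0.1056 without HUTU-80, 0.0611 without MDST8 and 0.1894 without NCI-H716, and KIF11 was at −0.60 without MDST8 and had adjusted p = 0.1137 without HUTU-80. Camera gave 4.06e-14 after adjustment, and adjusted p = 0.6626 with an estimated correlation. On the same arrays the difference between 3′ and 5′ probe sets was the highest of its line. For ACTB it was 2.019 in MDST8, against at most 1.539 on that line's other arrays, and 2.626 in NCI-H716, against at most 2.405. For GAPDH it was 0.383 against at most 0.324, and 0.351 against at most 0.325. These values stand beside each gene group with both clusters.

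Among 38 interferon-stimulated genes, IFI27 (1.80 ± 0.20), ISG15 (1.18 ± 0.20) and SAMD9 (1.13 ± 0.29) rose and IFIT5 (−0.67 ± 0.17) fell. IFI27 went from 2.88 to 4.58 in MDST8, both below background. In NCI-H716 it went from 3.65 to 5.63, its only value above background, so the size of its change is limited by background. SAMD9 was at 0.58 without NCI-H716 (adjusted p = 0.4155) and ISG15 at 0.75 without MDST8 (0.0761), and IFIT5 had adjusted p = 0.1261 without HUTU-80, 0.1408 without MDST8 and 0.2564 without NCI-H716. The list median of 0.224 had a camera adjusted p of 0.0160 and adjusted p = 0.7012 with an estimated correlation. The list median was 0.43 in MDST8 and −0.01 in NCI-H716, and without MDST8 the fitted median turned to −0.021 (adjusted p = 0.8160). The intestinal list (median 0.176, camera adjusted p = 0.0461) had 0 members past the threshold, and adjusted p = 0.7294 with an estimated correlation. Without NCI-H716 its median was 0.027, where nearly all members lay at background in the controls.

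Mesenchymal markers were not called as a list (median −0.081, camera adjusted p = 0.2533), but 5 of 49 fell, the probe set used for LOX, GREM1, a BMP antagonist (−1.44 ± 0.32), FSTL1 (−1.37 ± 0.24) and the intermediate filament gene VIM (−0.74 ± 0.18) among them. VIM was at −1.26 in NCI-H716 and −0.24 in MDST8, and its adjusted p of 0.0334 was 0.1107 without HUTU-80. Without NCI-H716, VIM was at −0.30 (adjusted p = 0.1249) and GREM1 at −0.76 (0.2486), and without HUTU-80 GREM1 had adjusted p = 0.1037. With the mean of all probe sets VIM was at −0.31 (0.4357), FSTL1 at −0.89 (0.0268) and GREM1 at −1.10 (0.0784), and the control level of GREM1 was 2.90 in MDST8, below background, and 5.53 in NCI-H716. Of 26 TGF-beta targets, CCN2 (1.16 ± 0.28) was among 2 that rose, and TGFB1 (−1.10 ± 0.22), HTRA1 (−1.09 ± 0.25) and BMPR2 (−0.66 ± 0.15) fell, with no list call (median 0.056). In NCI-H716 both values of CCN2 (3.59 and 5.30) and of HTRA1 (4.05 and 2.90) lay below background. CCN2 was at 0.68 without NCI-H716 (adjusted p = 0.2528) and had adjusted p = 0.0736 without HUTU-80, and HTRA1 had 0.0737 without HUTU-80, 0.1578 without MDST8 and 0.0629 without NCI-H716. Of 23 p53 targets, TP53I3 (0.97 ± 0.24) and AEN (0.57 ± 0.14) rose and SESN1 (−1.33 ± 0.18) and CCNG1 (−0.84 ± 0.14) were among 3 that fell, with no list call (median 0.169). CCNG1 was at −0.46 without NCI-H716. EPHB3 (−1.08 ± 0.24) fell among 23 Wnt targets (list median 0.056). Of 24 neuroendocrine markers (−0.018) only TPH1 passed, and it lay below background on every array (2.64 to 3.71), so no change of the gene is given. Of 43 ribosomal proteins, RPS9 (−0.28 ± 0.07), RPL12 (−0.28 ± 0.06), RPL3 (−0.24 ± 0.06) and RPL10A (−0.19 ± 0.05) fell, and the list was not called (median −0.025). Without NCI-H716, RPL12 was at −0.17 (adjusted p = 0.2656) and RPL3 at −0.15 (0.3362). No member passed among 25 immune cell markers (median −0.084, 0 by limma) and 20 endothelial cell markers (−0.038, 0 by limma). In these 2 lists the largest changes were −0.90 ± 0.31 for PTPN22 and 1.30 ± 0.41 for ROBO4, each with an unadjusted p under 0.05. The mean of the endothelial list was positive (0.042), and camera's direction was opposite to the median for the Wnt, neuroendocrine and endothelial lists.

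Limma called 1214 of 19774 genes with both clusters, 461 higher and 753 lower, and 4354 had an unadjusted p under 0.05. The count was 362 without HUTU-80, which has no such sample but enters the fit through its other arrays, 19 when only control and both-cluster samples were fitted, 662 with the mean of all probe sets and 679 without the trend of variance on level. Of 50 named genes past the threshold, 27 stayed past it without HUTU-80, a fit that keeps both samples with both clusters. Among them were ZEB1, VAMP8, PPM1F, CFL2, SEC23A, CDS1, PKP2, BUB1B and IFI27. Without MDST8 or NCI-H716 a single such sample is left, so a call kept or lost there rests on the spread of the other groups. Beside those given above, the call was lost without at least 1 line for LAMB3, ELOVL7, ZNF165, TMC4, PATJ, TET1, FSTL1, MCM2, TGFB1, BMPR2, TP53I3, AEN, EPHB3, RPS9 and RPL10A. With the mean of all probe sets it was also lost for CCN2, TGFB1, BMPR2, IFIT5, KIF11, TP53I3, RPS9, RPL12 and RPL10A, and EPHB3 was at −0.71. Among the genes that kept their call, IFI27 lay above background on only 1 array and TPH1 below it on every array.

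**Figure D2:**
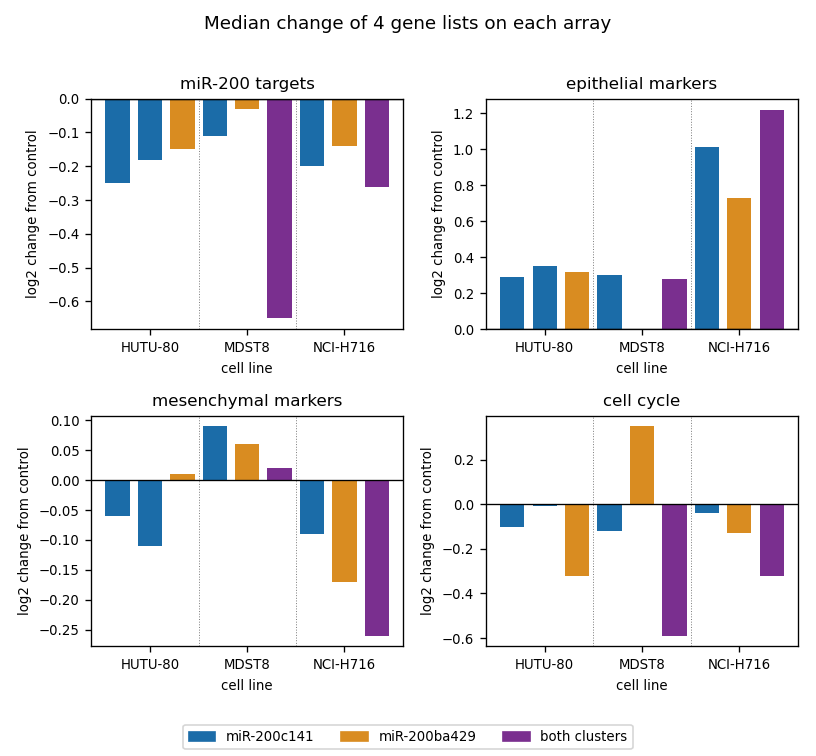
Median log2 change from the control array of the same line (vertical axis) of the miR-200 targets, epithelial markers, mesenchymal markers and cell cycle genes, with 1 bar per array, grouped by cell line and coloured by construct. Over all members, the epithelial medians of NCI-H716 run from 0.73 to 1.22, above those of the other lines, where more members lie at background. Over members above background on either array, the medians do not rank the lines, since a rise helps a member to pass and different members pass in each. They are 1.71, 0.09 and 2.13 in MDST8 with miR-200c141, miR-200ba429 and both clusters (10, 5 and 13 members). In NCI-H716 they are 1.19, 0.77 and 1.54 (38, 33 and 41 members). With both clusters the cell cycle medians are −0.59 in MDST8 and −0.32 in NCI-H716.

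A direct comparison of miR-200c141 with miR-200ba429 asked whether the clusters differed from each other. OSTM1 was lower with miR-200c141 by −1.08 ± 0.26 (SE, 3 lines each) and C3orf70 by −0.82 ± 0.18, and ACTR3C stood at 0.81 ± 0.20, while L1TD1 and OR5P3, of similar p, lay below background on every array. None of the 5 passed (adjusted p = 1.0000 for each). The epithelial genes were higher with miR-200c141 (median difference 0.306, 45 of 51 positive, camera adjusted p = 2.92e-07), and adjusted p = 0.3684 with an estimated correlation. The epithelial array medians were 0.29 and 0.35 with miR-200c141 against 0.32 with miR-200ba429 in HUTU-80, 0.30 against −0.00 in MDST8 and 1.01 against 0.73 in NCI-H716. Over members above background on either array, a filter that a rise helps to pass, they were higher with miR-200c141 in each line. In the same order they were 1.29 and 1.33 with miR-200c141 against 0.79, 1.71 against 0.09 and 1.19 against 0.77. The miR-200 targets were lower with it (−0.167, 35 of 45 negative, 7.63e-06), and adjusted p = 0.3454 with an estimated correlation. Interferon-stimulated genes (0.160, 3.81e-05), immune cell markers (0.096, 0.0181), mesenchymal markers (−0.044, 0.0188) and TGF-beta targets (−0.070, 0.0497) were called too, but 25, 23 and 25 of the 25 immune cell markers lay at background in the HUTU-80, MDST8 and NCI-H716 controls, so that call compares background signals. For these 4 lists, in the same order, adjusted p = 0.3454, adjusted p = 0.3454, adjusted p = 0.3684 and adjusted p = 0.5709 with an estimated correlation. Limma called 0 genes, and 705 had an unadjusted p under 0.05, fewer than the 989 expected by chance. Across genes, which are not independent replicates, the mean changes with the clusters correlated at r = 0.670 (Spearman's rho 0.606), where a shared control array alone gave 0.50 on average and at most 0.523 in 100 simulations. An average of 0.50 is what equal spread on every array gives. A control array of larger spread would raise it, so the higher r does not show agreement beyond the shared control.

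Cells with both clusters were also set against the mean of the single clusters, to ask what the double transduction changed further. MBTPS2, a protease that activates membrane-bound transcription factors, fell by 1.80 ± 0.14 on the log2 scale (SE, adjusted p = 0.0010), the spliceosome proteins SNRPB2 and DNAJC8 fell by 0.88 ± 0.08 and 1.38 ± 0.13, and the adapter protein YWHAG fell by 0.82 ± 0.07. The immediate early gene EGR1 rose by 1.68 ± 0.15, and these last 4 had an adjusted p of 0.0011. With the mean of all probe sets MBTPS2 (−0.72, adjusted p = 0.0780) and SNRPB2 (−0.32, 0.1769) did not pass. All 40 cell cycle genes had a negative difference (median −0.467), with 3 past the threshold over all genes and 27 adjusted over the list alone (camera adjusted p = 1.56e-18), and adjusted p = 0.3684 with an estimated correlation. Of the miR-200 targets 5 fell, and 12 fell adjusted over the list alone (median −0.393, camera 3.19e-09), with adjusted p = 0.3454 with an estimated correlation. The interferon-stimulated genes (0.295, 2 past the threshold, camera 1.05e-05) and epithelial genes (0.410, 0 past it, 3.81e-05) were higher, with adjusted p = 0.3454 and adjusted p = 0.4286 with an estimated correlation. The interferon median in MDST8 was 0.43 with both clusters against 0.12 and −0.15 with miR-200c141 and miR-200ba429, but in NCI-H716 −0.01 against −0.02 and −0.09. Over all members the epithelial median in NCI-H716 was 1.22 against 1.01 and 0.73, but in MDST8 0.28 against 0.30 and −0.00. Most members lay at background in MDST8. Over members above background on either array, a filter that a rise helps to pass, the MDST8 medians were 2.13 (13 members) against 1.71 (10) and 0.09 (5). In NCI-H716 they were 1.54 against 1.19 and 0.77. The RNA quality values given above for the arrays with both clusters apply here as well. Limma called 329 genes, 54 higher and 275 lower, and the count was 85 without HUTU-80, 577 without NCI-H716 and 139 without the MDST8 array with miR-200ba429, and without MDST8 31 genes were higher and 110 lower. It was also 118 with the mean of all probe sets, 98 without the variance trend, 154 when only these groups were fitted, 509 with the HUTU-80 arrays as separate samples, and 567 of the genes above the median level.

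The change with any construct was then compared between lines, with the constructs of a line as its replicates and 1 control array per line. ITGA2, the collagen-binding integrin alpha 2, differed between lines (adjusted p = 0.0288). Its mean change was 2.16 in HUTU-80 (SD 0.04 over 2 samples), from a control level of 4.87, −0.61 in MDST8 (SD 0.14 over 3), from 11.13, and 0.15 in NCI-H716 (SD 0.14 over 3), from 9.93. The HUTU-80 control of ITGA2 lay below background, and 1 of the 2 samples is the mean of the arrays titled 1:3 and 1:5 (7.16 and 6.86). The SD leave out the error of the control array, which all changes of a line share. The next genes did not pass. CEACAM5 (adjusted p = 0.0518), CAPN8 (0.0529), GPX2, an intestinal glutathione peroxidase (0.0801), and CEACAM6 (0.0828) were higher with a construct in NCI-H716, by 5.27, 4.72, 3.93 and 2.75, against −0.50 to 0.46 in the other lines. Each lay below background on every array of HUTU-80 and MDST8, so the values there compare background signals. CAPN8 lay below it in the NCI-H716 control as well (3.27). EPCAM (0.0529) stood at 5.47 in HUTU-80, 2.77 in NCI-H716 and −0.16 in MDST8. DYDC2 (0.0529) and NRIP2 (0.0828) lay below background on every array. Limma called this 1 gene, and 987 had an unadjusted p under 0.05, where 989 are expected by chance. The count was 0 without the HUTU-80 array titled 1:3, without the variance trend and without HUTU-80, 31 without the MDST8 array with miR-200ba429, 14 with the HUTU-80 arrays as separate samples, 7 without the array titled 1:5, 5 after median centring, 4 without MDST8 and 3 with the mean of all probe sets.

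Of the 2 HUTU-80 arrays with miR-200c141, the array titled 1:3 had ZEB1 at −1.95 and that titled 1:5 at −1.88, with EPCAM at 5.94 and 6.21, CDH1 at 2.81 and 2.65, and VAMP8 at 3.75 and 3.73 in the same order. Others lay further apart or differed in sign, such as ZEB2 (−1.63 and −0.65), C14orf132 (−1.44 and −0.68), GREM1 (−0.08 and −1.13), IFIT1 (−0.89 and 1.21) and IFI6 (−0.57 and 0.70). The SD of their difference across genes was 0.275, and 72 genes lay over 1 log2 unit apart. Across genes, which are not independent replicates, their changes correlated at r = 0.670 (Spearman's rho 0.576), where the shared control array alone gave 0.50 on average and at most 0.521 in 100 simulations. The limit given above for such simulations, equal spread on every array, holds here as well. The arrays titled 1:3 and 1:5 are single arrays, so no test was made.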

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

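Of the tests in this part, those on both clusters in MDST8, on silent epithelial genes, on exchanged arrays, on the interferon list and on RNA quality were chosen only after the result was seen.

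The first pattern is that CDH1 and EPCAM stayed near background in MDST8, with changes of −0.12, 0.62 and 0.08 for CDH1 and −0.22, −0.14 and −0.12 for EPCAM with miR-200c141, miR-200ba429 and both clusters. The values argue against the explanation that epithelial genes at background in a control cannot rise in general. Of 28 such genes in NCI-H716, 18 stood over 1 log2 unit higher with miR-200c141. Of 46 such genes in MDST8, 8 did so with miR-200c141, 0 with miR-200ba429 and 10 with both clusters. This does not cover CDH1 and EPCAM themselves in MDST8. Weak miR-200 activity stays open for miR-200c141, where the 119 genes at −0.5 or lower in both other lines and above background in the MDST8 control had a median of −0.21 in MDST8 (quartiles −0.48 and −0.04), although the same test gave −0.41 in HUTU-80 and −0.37 in NCI-H716, short of −0.5 as well, and on that MDST8 array ZEB1 was at −1.45, VAMP8 at 5.35 and 12 epithelial genes over 1 higher. It is argued against for both clusters, where the same genes had a median of −0.92 while CDH1 and EPCAM stayed low. That argument is limited, because this array had the highest 3′ to 5′ differences of its line, and a part of RNA quality in the fall was not tested. A difference between the lines, such as the state of these genes' promoters, may contribute and was not tested.

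The second pattern is that in MDST8 with miR-200ba429 ZEB1 (−0.13) and VAMP8 (0.20) stayed close to the control and 0 epithelial genes were over 1 log2 unit higher, where HUTU-80 and NCI-H716 had −1.13 and −1.29, 2.78 and 3.75, and 13 and 20 genes, although 71 genes in all were over 1 higher and 167 lower, against 138 and 68 on the HUTU-80 array titled 1:5. That MDST8 does not respond to miR-200 met its planned bound with miR-200c141 (median −0.21). HUTU-80 (−0.41) and NCI-H716 (−0.37) met that bound too in the same test, so it cannot set MDST8 apart. This qualification was made after the values were seen. On the MDST8 array with miR-200c141, ZEB1 was at −1.45 and VAMP8 at 5.35. Of 51 epithelial genes, 12 were over 1 log2 unit higher there and 0 lower. Genes lowered by miR-200ba429 in both other lines had a median of −0.83 in MDST8 with both clusters. Both sets of values, each from a single array, argue against a lack of response. The limit of RNA quality on the array with both clusters holds here as well. Weak activity of the construct in that sample also met its planned bound (median −0.14 over 91 genes, chosen in the same way), yet NCI-H716 gave −0.16 and HUTU-80 −0.32 in the same test, a qualification made after the values were seen; the changes of ZEB1, VAMP8 and the epithelial genes were smaller than in the other lines, but weak activity of the construct and a lower response of this line to this cluster cannot be told apart. An exchange of the control and miR-200ba429 arrays of MDST8 cannot be told apart from correct labels, because ZEB1 differed by 0.128, within the residual SD of 0.387; every other array of the line was over 1 higher than the control in 29 genes and lower in 51, against 19 and 3 for the miR-200ba429 array in its place, which leans away from an exchange, but the spread of such counts is not known.

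The third pattern is that more genes changed with both clusters (1214) than with either alone (0 by limma for each, 1302 and 1214 at an unadjusted p under 0.05). An interferon response to a second transduction and its absence cannot be told apart, because the list median of −0.01 in NCI-H716 (0.43 in MDST8) met the bound set against it, but 22 of the 38 members lay at background in that control, and the 17 above background there or with both clusters went both ways (median 0.10, quartiles −0.37 and 0.55), a qualification made after the values were seen. Lower RNA integrity in the double-transduced samples stays open, because the 3′ to 5′ difference was the highest of its line in 4 of 4 comparisons. These come from only 2 arrays. For ACTB it was 2.019 in MDST8, against at most 1.539 on the line's other arrays, and 2.626 in NCI-H716, against at most 2.405. The HUTU-80 arrays, none with both clusters, ran from 2.102 to 2.388. The sum of the single-cluster changes and a larger effect cannot be told apart, since the median excess over the sum was 0.27 in MDST8 (quartiles −0.146 and 0.748) and 0.029 in NCI-H716 (−0.246 and 0.328). A higher total amount of miR-200 may contribute and was not tested.

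Chance in the grouping of arrays was examined with genes at an unadjusted p under 0.05. For any construct, 4 of the 48 choices of 1 array per line as the control gave as many genes as the real 1851, so chance cannot be excluded; the highest other, 3455, took both both-cluster arrays and the HUTU-80 array with miR-200ba429 as controls, which points to how far the both-cluster arrays stand apart. For the difference between lines 20 of 48 choices gave 987 or more, so chance cannot be excluded, and the highest other, 3601, took the MDST8 array with both clusters as that line's control. The other comparisons have 10 splits of 6 samples, too few for a share under 0.05. With only those samples fitted, miR-200c141 against control gave 1602 genes (highest other 1689, 3 splits as large), miR-200ba429 against control 1351 (1467, 3 splits) and miR-200c141 against miR-200ba429 997 (1571, 6 splits). Only 4 of the 10 splits, the real one included, keep 1 sample of each line on each side, and the highest other of these gave 720, 1098 and 1107 in the same order.

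The change of ITGA2 differed between lines by the interaction test (adjusted p = 0.0288). Over all members, 3 lists had array medians of one sign in MDST8 and of the other in NCI-H716, a difference that was not tested. Mean array medians in MDST8 and NCI-H716 were 0.05 and −0.18 for mesenchymal markers, −0.16 and 0.27 for TGF-beta targets, and 0.09 and −0.12 for neuroendocrine markers. Over members above background on either array, only the TGF-beta targets kept opposite signs. In MDST8 with miR-200c141, miR-200ba429 and both clusters, the mesenchymal medians were then −0.05, 0.00 and −0.03. The neuroendocrine medians were −0.25, −0.17 and −0.50 there, and −0.06, −0.16 and −0.18 in NCI-H716.

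Among the 4 arrays with miR-200c141, Dixon's test set 9 of 55 values apart from the others, where chance gives about 2.8 for independent arrays; 2 of the 4 are the HUTU-80 pair, which share a line and a control, so that rate does not hold here. In NCI-H716 these were changes of 1.89 for CDKN1A, 5.25 for CEACAM5, 2.28 for DKK1, 4.62 for ESRP1 and 3.43 for REG4, and list medians of 1.01 for epithelial markers and 0.35 for intestinal differentiation genes. In MDST8 these were changes of −3.06 for PRRX1 and −1.42 for PTPN22. Over members above background on either array, the epithelial medians were 1.19 in NCI-H716 (38 members), 1.29 and 1.33 in HUTU-80 (20 on each array) and 1.71 in MDST8 (10). A rise helps a member to pass that filter, and different members pass in each line, so these medians do not rank the lines. Among 12835 probe sets with no gene name, 146 were past the threshold with both clusters, 73 higher and 73 lower. With miR-200c141 4 were past it, 3 higher and 1 lower, and with miR-200ba429 or any construct 0.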

How the results depend on the processing

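The fit without the MDST8 array with miR-200ba429 was chosen only after the data were seen, and the other tests of this part were planned. For the counts of genes and for the miR-200 target and epithelial lists, 159 alternative values stayed within 1.5 times the count or on the same side of the threshold, 32 counts moved further and 14 list calls were lost. For single genes and the other lists, 2668 kept their direction and their side of the threshold, whatever the size of the change, 243 were no longer past the threshold, 55 newly past it and 27 turned in sign. A result not past the threshold in the main fit counts as kept when it stays so, and of the named-gene results 147 were of this kind and 55 were called. Of the 55, 53 lost the call and 2 turned with no block for cell line. With only the groups compared 43 lost it, with the mean of all probe sets 17 and without the variance trend 15. Each other setting that kept all lines lost at most 4. The causes were not tested unless stated. Immune and endothelial markers have no value among genes above the median level, since no member is left there. Of the epithelial genes, 40 in HUTU-80, 46 in MDST8 and 28 in NCI-H716 lay at background in the control, so their changes are limited by the signal there.

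With both clusters against control the count of 1214 genes became 0 with no block for cell line, 662 with the mean of all probe sets, 679 without the variance trend and 19 when only those groups were fitted, where fewer samples estimate the spread. It ran from 362 to 971 when each line was left out, 362 without HUTU-80. Both clusters against the mean of single clusters, 329 genes, gave 0 with no block for cell line, 509 with the HUTU-80 arrays separate, 118 with the mean of probe sets, 567 among genes above the median level, 98 without the trend, 154 with only those groups, 139 without the MDST8 array with miR-200ba429, and 85 to 577 with lines left out. For miR-200c141 the count of 0 (limma, 1302 at an unadjusted p under 0.05) became 3 with the HUTU-80 arrays separate, 4 with only those groups, 3 without the MDST8 array with miR-200ba429 and 0 to 22 with lines left out. For any construct 0 (1851 at an unadjusted p under 0.05) became 3 without that array and 0 to 8 with lines left out, and for miR-200ba429 0 (1214) became 0 to 6. The count of 1 gene that differed between lines became 14 with the HUTU-80 arrays separate, 7 with only the array titled 1:3, 0 with only that titled 1:5, 3 with the mean of probe sets, 5 after median centring, 0 without the trend, 31 without the MDST8 array with miR-200ba429 and 0 to 4 with lines left out.

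List medians are the same with an estimated correlation and with fry, but no call held. For epithelial markers the adjusted p were 0.3745 and 0.1787 for any construct (median 0.631), for miR-200c141 (0.734) and for both clusters (1.138), and 0.4574 and 0.3906 for miR-200ba429 (0.360). For miR-200 targets they were 0.7012 and 0.4522 for any construct (−0.231), 0.3745 and 0.2990 for miR-200c141 (−0.197), and 0.3745 and 0.0879 for both clusters (−0.450).

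Signs turned as follows. With no block for cell line, FN1 for any construct was −0.35, and with both clusters CCN2 was −0.59 and IFIT5 0.24. FN1 for any construct was −0.01 with the HUTU-80 arrays separate, −0.00 after median centring and −0.01 without the MDST8 array with miR-200ba429, where CDT1 for miR-200ba429 was −0.07. With the mean of probe sets, ZEB2 was 0.08, VIM 0.17 and MMRN2 0.02 for miR-200ba429. With lines left out, FN1 ran from −0.13 to 0.12 for any construct, −0.12 to 0.13 for miR-200c141 and −0.10 to 0.51 for miR-200ba429. ESRP1 ran from −0.11 to 2.32, −0.07 to 2.40, −0.18 to 1.28 and, with both clusters, −0.03 to 4.57. CEACAM5 ran from −0.38 to 2.68, −0.41 to 2.43, −0.30 to 2.27 and −0.46 to 4.27 in the same order, the lowest without NCI-H716. For miR-200c141, CDH2 ran from −0.27 to 0.03, PRRX1 from −1.57 to 0.16 and DKK1 from −0.08 to 1.14. CDT1 for miR-200ba429 ran from −0.05 to 0.44, and the interferon median with both clusters from −0.021 without MDST8 to 0.419 without NCI-H716.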

Other observations

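The counts within lines and the transfer of changes between lines were computed only after the data were seen. Epithelial genes over 1 log2 unit higher than the control of the line numbered 14 on each HUTU-80 array with miR-200c141 and 13 with miR-200ba429. In NCI-H716 they numbered 26 with miR-200c141, 20 with miR-200ba429 and 29 with both clusters, and in MDST8 12, 0 and 15 in that order. Of the miR-200 targets, 17 were over 1 lower in MDST8 with both clusters and 8 in NCI-H716 with both. In MDST8 the cell cycle median was 0.35 with miR-200ba429 and −0.59 with both clusters. The p53 targets had medians of 0.34 in HUTU-80 with miR-200ba429 and 0.35 in MDST8 with both clusters, against −0.17 in NCI-H716 with both. DCN was at −2.48, −2.46 and −2.43 in MDST8 with miR-200c141, miR-200ba429 and both clusters, and PRRX1 at −3.06, −1.65 and −3.89, but the DCN control of MDST8 lay at 5.48, near background, and the mesenchymal list had array medians of 0.09, 0.06 and 0.02 there. Over mesenchymal members above background on either array, the MDST8 medians were −0.05, 0.00 and −0.03 in the same order. All of these are values of single arrays with no test.

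Genes at −0.5 or lower with miR-200c141 in both other lines, and above background in the control of the line left out, had a median of −0.41 in HUTU-80 (74 genes, 94.6% of them negative), −0.21 in MDST8 (119 genes, 79.0%) and −0.37 in NCI-H716 (53 genes, 73.6%). Genes at 0.5 or higher in both other lines, at any control level, had medians of 0.27, 0.23 and 0.40 in the same order. With miR-200ba429 the genes at −0.5 or lower had medians of −0.32, −0.14 and −0.16, and those at 0.5 or higher 0.05, −0.04 and 0.15, of which 52.6%, 46.7% and 67.3% were positive. The control of the line left out serves both as the filter and as the baseline of the lower genes, which draws their medians down; with the filter on the array of the other single cluster they were −0.36, −0.19 and −0.37 with miR-200c141 and −0.18, −0.13 and −0.10 with miR-200ba429, and the same genes in MDST8 with both clusters had −0.90 and −0.79.

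In HUTU-80, 74 genes were over 1 log2 unit higher and 22 lower on every construct array than on the control, and the same count with another array in the control's place gave at most 5 higher and 32 lower. In NCI-H716 the control gave 128 higher and 57 lower, and the array with both clusters in its place 59 and 61. In MDST8 the control gave 29 and 51, fewer than the array with both clusters in its place, which gave 285 and 205, while the miR-200ba429 array gave 19 and 3 and the miR-200c141 array 7 and 17.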
